A study of Mus musculus with 12 samples.

How the data were processed

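RNA sequencing was done on natural killer (NK) cells sorted from C57BL/6 mice, in 12 libraries: 3 labelled wild type (WT) and 3 labelled Rfx7 knockout (KO) from each of spleen and bone marrow. Per the labels' protocols, the knockout animals carry Vav-Cre with both Rfx7 copies floxed, which removes the gene's floxed part in blood cells, and the wild-type animals carry the same Cre with unfloxed Rfx7. Per the labels' protocols, NK cells were enriched with a bead kit and sorted as CD3-negative, CD19-negative cells, with the markers NK1.1 and Ncr1 for spleen and NK1.1 and CD122 for bone marrow. Per the labels' protocols, spleen libraries were made with SMART-Seq v4 and Nextera XT and bone marrow libraries with a TruSeq stranded mRNA kit. Organ, kit and gate therefore go together, and no level was compared between organs; only the difference of the genotype effects was. The labels do not say that replicates are separate animals, so the p-values measure the spread between these libraries, which may be partly technical.

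The deposited values are log2(RPKM + 1), made by the authors, as the values themselves show: one file per library, with 21554 gene symbols in the same order. Per the submitters' processing notes, cutadapt, STAR, featureCounts, R 3.1.0 and edgeR were used by the authors, with the builds GRCm38 and mm10 named; the role of each, other versions, the annotation and the strand setting are not given in the sources used here. A gene with no reads is listed at exactly 0. RPKM scales by gene length and by an effective library size, so values of low genes are compressed by the pseudocount of 1 RPKM, and a fold change on this scale understates the change of low genes.

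The reads behind the values were worked back, because 2^value minus 1 of a gene steps by what 1 read is worth. Gene lengths were taken from GENCODE M21 exon unions where these gave whole reads in every library (7336 genes) and otherwise searched for (8204 genes). All 15540 genes with reads gave whole reads within 1e-06 of a read plus a relative 1e-09; 6014 genes had none. A first tolerance of 0.01 read was tightened after it was found that a searched length could meet it by chance in genes with few reads. On simulated reads, 99.97% of the 11502 genes with at least 100 reads were recovered exactly, and 95.38% of the 3748 genes with 1 to 99 reads. The recovered total was 14046159 to 21690945 reads per spleen library and 24385839 to 30979552 per bone marrow library. A count of 3 reads, the limit that a count of 0 allows, is at most 0.21 CPM in any library; this covers counting error only, since PCR copies are not independent molecules.

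The design written before the data were examined assumed read counts and a count model. Since the deposited values are normalized, the test was changed to limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on the deposited log2 values, per organ, with the genotype label as the only term. Genes with a mean value of at least 1 over the organ's 6 libraries were tested, and Benjamini-Hochberg adjusted p of at most 0.05 was the threshold. The difference between organs was the interaction contrast in a fit of all 12 libraries. Gene lists (33, fixed before the data were examined) were tested with camera at a preset correlation of 0.01 when at least 3 members were tested; camera with an estimated correlation and fry were alternatives. The list of sex genes was kept out of the list test. Tp53inp1 in the list of RFX7 candidate targets had no match under that name, since the files write Trp53inp1; the list was left as fixed. Coordinates are from GENCODE M21 on GRCm38, which 20434 of the 21554 symbols match.

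Named genes follow a rule fixed before the data were examined: Rfx7; per organ the 8 called genes with the largest change each way, with mean CPM of at least 4, no overlap between the groups and no predicted symbol; up to 4 called members of each list; up to 8 genes each way called in both organs; and 12 genes of NK biology whatever their values. Others are said to be chosen after their values were seen.

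The fits were tested on simulated data with a dispersion of 0.02. In each organ 200 genes, drawn from genes well above the filter, were changed. The RFX7 candidate targets were also lowered 2-fold in both organs and count among the genes changed 2-fold within an organ. In spleen, 52.2% of the 67 genes changed 1.5-fold were found and 98.8% of the 82 changed 2-fold, among 9382 tested genes. In bone marrow the shares were 61.2% of 67 and 100% of 82, among 9481. For the difference between organs, 20% of 130 genes changed 1.5-fold and 81.4% of 129 changed 2-fold were found, among 9503. False calls were 13 of 195 calls in spleen, 15 of 204 in bone marrow and 14 of 279 for the difference. The simulated genes varied independently, and few changed genes lay near the filter. The shares found therefore overstate what the fits find among low genes. Alternatives covered scaling, the low-value filter, the pseudocount, limma-voom on the recovered reads, thinning to the smallest library, a gene length correction, a neutrophil covariate, a replicate block and leaving out each library. DESeq2 was planned as an alternative and was not run: no count model was used, since the deposited unit is not counts, and the recovered reads were tested with limma-voom instead.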

Results

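The series holds RNA-seq of NK cells, cytotoxic lymphocytes of the innate immune system, from spleen and bone marrow of mice labelled WT or KO for the transcription factor gene Rfx7 in blood cells. Each of the 4 groups (spleen WT, spleen KO, bone marrow WT, bone marrow KO) has 3 libraries. Values are the deposited log2(RPKM + 1), and the depth behind them was 14046159 to 21690945 reads per library in spleen and 24385839 to 30979552 in bone marrow. No pair of libraries within a group agreed within sampling noise; the chi-square per degree of freedom ran from 14.3 to 95.2.

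The targeted gene was examined first. Rfx7 (chromosome 9, 72532240 to 72622937, GRCm38) was not lower in the libraries labelled KO. In spleen its level was 1.70 ± 0.16 (SD, n = 3) in WT and 2.20 ± 0.09 (SD, n = 3) in KO, a log2 fold change of 0.50 ± 0.14 (SE) with an adjusted p of 0.138 from limma, and all 3 KO-labelled libraries lay above all 3 WT. In bone marrow it was 3.26 ± 0.07 in WT and 3.38 ± 0.21 in KO (SD, n = 3), a log2 fold change of 0.13 ± 0.13 (SE). The values are for the whole gene and the labels do not give the floxed part, so they neither show nor exclude its loss. Directions below are therefore those of libraries labelled KO against libraries labelled WT. In spleen, limma-voom with quality weights gave Rfx7 an adjusted p of 0.0071 and the higher level in the KO-labelled libraries.

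**Figure D1:**
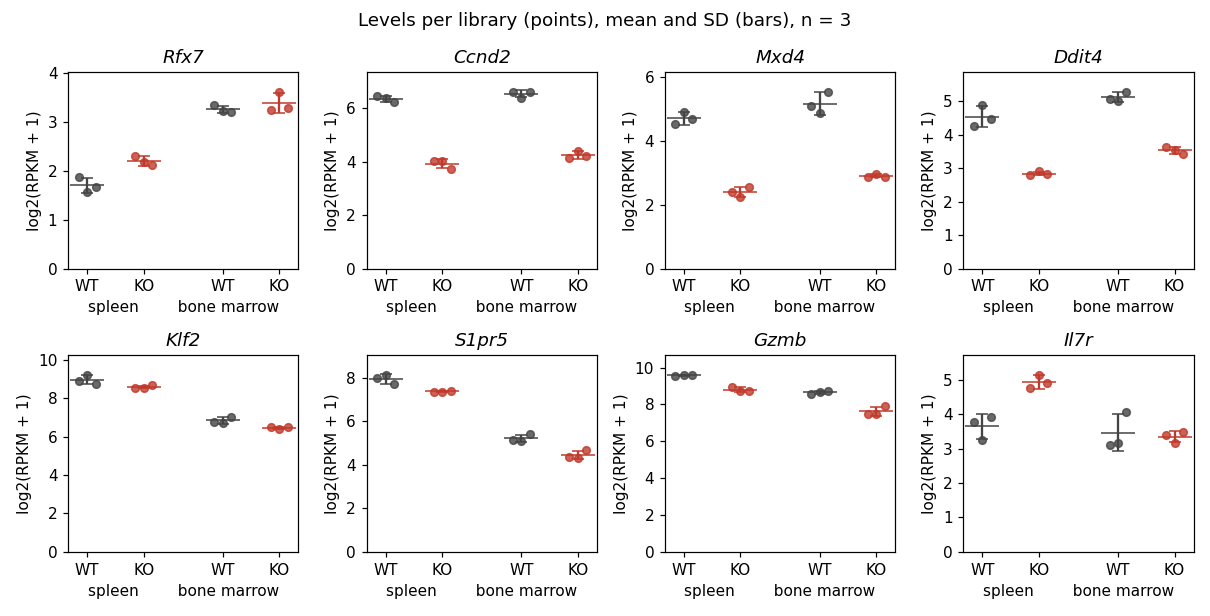
Level of 8 genes as log2(RPKM + 1) in each library (points), with the mean and SD of the 3 libraries of a group (bars), by organ and genotype label. Ccnd2, Mxd4 and Ddit4 are lower in every KO-labelled library of both organs, while Rfx7 is not lower.

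What the KO label changes in spleen NK cells was asked next. The largest decreases were in Ccnd2, which encodes the cell cycle protein cyclin D2 (chromosome 6, 127125162 to 127152193), at 6.36 ± 0.10 in WT and 3.93 ± 0.18 in KO (SD, n = 3), and in Mxd4, a repressor that competes with MYC for its partner MAX (chromosome 5, 34173883 to 34187720), at 4.70 ± 0.20 and 2.38 ± 0.16 (SD, n = 3). Their log2 fold changes were -2.43 ± 0.13 and -2.31 ± 0.15 (SE; adjusted p = 4.2e-06 and 1.4e-05). Col8a2 fell by 2.21, Ddit4, an inhibitor of mTORC1 signalling, by 1.70, Dyrk1b by 1.65, Ptms by 1.59, Ifi27l2a by 1.48 and Irs2 by 1.35 on the log2 scale. Higher in KO-labelled spleen were Il7r, the interleukin-7 receptor (log2 fold change 1.28 ± 0.18, SE), Kit, the stem cell factor receptor (1.17 ± 0.15), Slamf6 (1.07), Plxnc1 (1.04), Cd22 (1.02), Rhpn1 (0.99), Aqp9 (0.96) and Avil (0.88). Gzmb, which encodes granzyme B of the cytotoxic granules, fell by 0.78, Tob1 by 1.24, C1qb, a macrophage complement gene, by 1.10, Bbc3, which encodes the cell death protein PUMA, by 1.09, Rfx5 by 0.76 and the heat shock gene Dnajb1 by 0.67.

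limma called 60 of 9322 genes in spleen, 25 higher and 35 lower. The balance was kept under most alternatives but turned under some, among them library totals alone (37 higher and 33 lower), limma-voom (35 and 30), limma-voom with quality weights (516 and 317) and a gene length correction (39 and 34). Of the tested genes 20.2% had no overlap in CPM between the groups, where chance gives 10% per gene. CPM leaves out the composition factor, which ran from 1.01 to 1.06 in WT and 1.07 to 1.11 in KO-labelled spleen. Genes also vary together, so the 10% is a loose benchmark for the share. The count rests on single libraries: it was 28 without WT replicate 1, 30 without WT replicate 3, and 9, all lower, without KO replicate 2. The 9 genes called without each library in turn were Ccnd2, Col8a2, Ddit4, Dyrk1b, Ifi27l2a, Mxd4, Tsc22d1, Ucp2 and Wdr6; Tsc22d1 and Wdr6 were chosen after their values were seen. Every higher call, Il7r and Kit included, was lost without KO replicate 2.

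Genes that act in growth restraint and quiescence were lower in KO-labelled spleen. Of 23 tested members 6 fell and none rose past the threshold, and 12 were lower when adjusted over the list alone, with 2 higher; Mxd4, Ddit4, Pik3ip1 (log2 fold change -0.98) and Btg2 (-0.75) were among the called members. The list of RFX7 candidate targets from human cell studies, had 5 of 16 members lower and none higher, and 9 lower when adjusted over the list alone. The lists are not independent: of its called members Mxd4, Ddit4, Pik3ip1 and Tob1 are also called members of the quiescence list, and Rfx5 alone is not. The adjusted p from camera was 3.1e-06 for quiescence and 8.0e-09 for the RFX7 candidates; with an estimated correlation the adjusted p was 0.075 for both. Genes typical of immature NK cells were higher: Il7r, Kit and Tcf7 (0.65), a transcription factor of early lymphocytes, rose among 14 tested members, and 6 were higher adjusted over the list alone (adjusted p = 1.4e-07; adjusted p = 0.112 with an estimated correlation). Innate lymphoid cell markers, which share Il7r with that list, had positive fold changes in all 9 tested members, with Il7r the called one (adjusted p = 9.5e-09; adjusted p = 0.084 with an estimated correlation). T cell markers, whose 5 tested members are named after their values were seen, moved with these lists in part. None passed the threshold over all genes, but Cd3d (log2 fold change 0.66), Trat1 (0.60) and Cd3g (0.32) were higher adjusted over the list alone and in all 3 KO-labelled libraries, while Cd3e (-0.15) and Lat (-0.26) overlapped between the groups. The T cell list had an adjusted p of 0.051 from camera, 0.312 with an estimated correlation and 0.024 from fry. The adjusted p from fry was 0.0016 for quiescence and for the RFX7 candidates. It was 0.021 for immature NK and for innate lymphoid cell markers. Ribosome biogenesis genes were higher, with 19 of 26 positive and a median of 0.17. Their adjusted p was 0.0039 from camera, 0.116 with an estimated correlation and 0.024 from fry. DNA replication genes were lower, with 17 of 22 negative and a median of -0.12. Their adjusted p was 0.039 from camera, 0.471 with an estimated correlation and 0.121 from fry. No member of these lists was called.

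Genes of oxidative phosphorylation had lower values in KO-labelled spleen as a group, with a median log2 fold change of -0.29 over 72 genes, 67 of them negative, and no member past the threshold. The list passed camera (adjusted p = 9.5e-09), but the adjusted p was 0.471 with an estimated correlation. Spleen fold changes also followed gene length across genes (Spearman rho = 0.37 over 9322 genes, which are not independent replicates): the median was -0.20 in the shortest eighth and 0.095 in the longest.

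In bone marrow NK cells, asked the same question, every called gene was lower in the libraries labelled KO. Ccnd2 was 6.55 ± 0.13 in WT and 4.27 ± 0.14 in KO (SD, n = 3), a log2 fold change of -2.28 ± 0.11 (SE; adjusted p = 0.00027). Mxd4 fell by 2.26, Col8a2 by 1.79, Ptms by 1.75, Dyrk1b by 1.69, Tob1, an antiproliferative factor, by 1.62, Ddit4 by 1.59 and H2-Oa, a regulator of MHC class II peptide loading, by 1.45. Gzmb fell by 1.02 and Rfx5, a transcription factor of MHC class II genes, by 1.08. limma called 16 of 9553 genes, 0 higher and 16 lower, and 361 genes had an unadjusted p under 0.05, of which 160 were higher, where 478 are expected by chance. Of the tested genes 7.8% had no overlap in CPM between the groups, against 10% per gene by chance. The count was 8 without WT replicate 1, 9 without WT replicate 2 and 9 without KO replicate 1. Ccnd2, Col8a2, Cxcl10, Ddit4, Dyrk1b, Mxd4, Ptms and Tob1 were called without each library in turn, and the other 8 calls, Gzmb and Rfx5 among them, were lost without at least 1 library. Ucp2, Gadd45g and Trp53inp1, with Isg15 and Ifit1 given below, complete the 16; Gadd45g and Trp53inp1 were named after their values were seen.

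Interferon response genes were lower in KO-labelled bone marrow. All 17 tested members had a negative fold change; Cxcl10 (log2 fold change -1.44 ± 0.12, SE), Isg15 (-1.05 ± 0.12) and Ifit1 (-0.97 ± 0.13) fell, and 12 members were lower when adjusted over the list alone. The Isg15 call was lost without WT replicate 1, WT replicate 2 or KO replicate 1 and the Ifit1 call whichever of the 6 was left out. The RFX7 candidates had 4 of 16 members lower, 11 adjusted over the list alone, and quiescence genes 3 of 24 lower, 12 adjusted over the list alone. The adjusted p from camera was 2.8e-30 for interferon response, 3.8e-32 for the RFX7 candidates and 1.5e-25 for quiescence; the adjusted p was 0.051 for each with an estimated correlation. Markers of neutrophils, which the sort was not meant to keep, varied among these libraries: their summed level was 3140, 3218 and 149 CPM in WT and 7768, 1837 and 3380 CPM in KO. All 15 had positive fold changes, with a median of 1.56 and none past the threshold. The list had a camera adjusted p of 8.9e-08, and 0.529 with an estimated correlation. Leaving out 1 library moved the camera adjusted p between 8.9e-16 and 0.103.

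**Figure D2:**
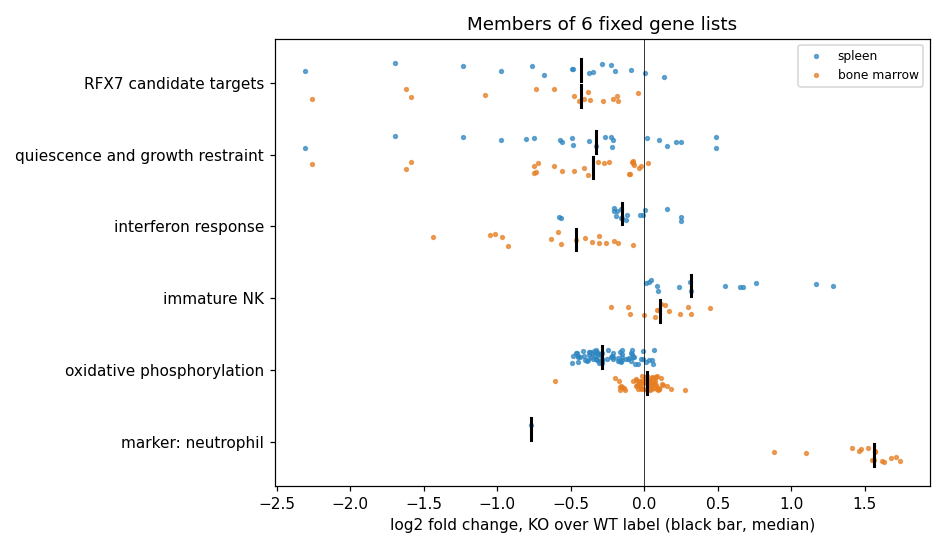
log2 fold change, KO over WT label, of each tested member (points) and the median (black bar) of 6 fixed gene lists in spleen and bone marrow. All 17 interferon response members lie below 0 in bone marrow.

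Whether the organs responded alike was asked through the genes called in both and through the difference of the effects. Called lower in both organs were 10 genes, Ccnd2, Mxd4, Col8a2, Dyrk1b, Ddit4, Ptms, Tob1, Ucp2, Gzmb and Rfx5, where 0.051 would be shared if the calls were independent (one-sided Fisher's exact p = 1.6e-22); none was called higher in both or in opposite directions. The Fisher p treats genes as independent units, which they are not, and does not measure the spread between libraries. The shared count was 6 without spleen WT replicate 1 and 6 without spleen KO replicate 2. Of 49 genes called in spleen and tested in bone marrow, 46 had the same sign there, and all 16 called in bone marrow had the same sign in spleen. Over 9032 genes the fold changes correlated across genes with Pearson r = 0.37 and Spearman rho = 0.27.

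**Figure D3:**
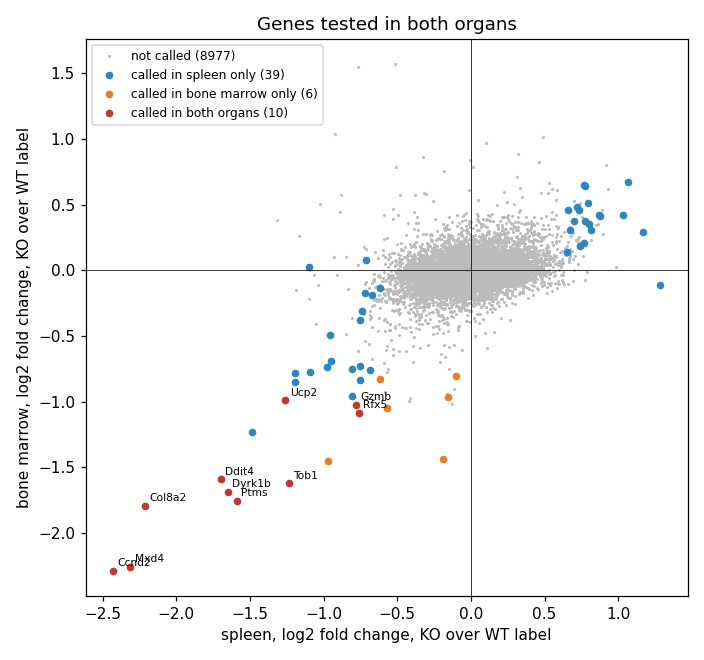
log2 fold change, KO over WT label, in bone marrow against spleen for the genes tested in both organs, coloured by where limma called them. The 10 genes called in both lie in the lower left.

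The test of the difference called 0 of 9499 genes with limma, with 424 at an unadjusted p under 0.05, where 475 are expected by chance, and 0 with limma-voom. Without spleen WT replicate 3 it called 1 gene, Cxcl10, whose fold change was lower in bone marrow. A gene called in one organ, such as Il7r in spleen (log2 fold change -0.11 in bone marrow), was therefore not shown to respond differently.

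Of the 12 genes of NK biology fixed in advance, Il7r in spleen passed the threshold, as given above, and no other passed in the main fit of an organ where it was tested; under some alternatives Mki67 (higher), S1pr5 and Slc3a2 (lower) passed in spleen and S1pr5 (lower) in bone marrow. Klf2, a transcription factor of lymphocyte quiescence and homing, had log2 fold changes of -0.37 ± 0.14 in spleen and -0.38 ± 0.11 in bone marrow (SE; adjusted p = 0.221 and 0.725), and S1pr5, the receptor that guides NK cells out of bone marrow, -0.57 ± 0.13 and -0.77 ± 0.13 (adjusted p = 0.089 and 0.133). Both, and Slc3a2 (-0.60 and -0.21; adjusted p = 0.075 in spleen), were lower in all 3 KO-labelled libraries than in any WT library of each organ without passing the threshold, as were Tbx21 and Bcl2 in spleen only. Sell (0.03 and -0.18), Klrg1 (0.19 and 0.35), Cd27 (0.03 and -0.00), Eomes (0.00 and -0.12), Tbx21 (-0.34 and -0.28), Mki67 (0.54 and 0.39) and Bcl2 (-0.36 and -0.18) did not pass in spleen or bone marrow; the signs of Sell, Cd27 and Eomes in spleen and Cd27, Il7r and Mki67 in bone marrow changed with the setting or the library left out. Tfrc was below the filter in spleen and not called in bone marrow (0.26).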

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

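The tests of explanations and the list test of the difference between the organs were chosen after the data were seen; the splits of the libraries were fixed before their results, and leaving out each library and the estimated correlation were planned for the lists within each organ.

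Rfx7 was not lower in the libraries labelled KO. An exchange of single libraries is argued against: in the mean level of the RFX7 candidate targets, 0 of 12 libraries lay inside or beyond the range of the other group of their organ. An exchange of all labels is argued against too, as far as those genes are activated by RFX7, since their median log2 fold change was -0.43 in the organ where it was nearest to 0. A candidate explanation that stays open is a deleted part that whole-gene values do not resolve: the RPKM ratio in spleen was 1.59, and no value of the floxed part was at hand.

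Interferon response genes differed between the organs in a test of the difference (camera adjusted p = 9.1e-11, and 0.086 with an estimated correlation). The median log2 fold change was -0.47 in bone marrow and -0.15 in spleen. Spleen leaned the same way, with 13 of 17 tested members negative and none past the threshold (camera adjusted p = 0.210). The difference is thus one of size, and a lack of response in spleen was not shown. Neutrophil content is argued against within a limit: with the neutrophil marker level as a covariate the bone marrow median was -0.52. The slope of that covariate rests largely on WT replicate 3, with 149 CPM of these markers against 3140 and 3218 CPM in the other WT libraries. A single library that stands apart is argued against as well, since the median nearest to 0 among the fits that leave out 1 library was -0.39. The genotype, and a shared day, litter or housing that the labels do not give, may account for the lower values in bone marrow and were not tested apart. Library kit and sorting gate go with the organ. For this list and those below, a difference between the organs cannot be told apart from a difference of kit or gate.

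Oxidative phosphorylation genes also differed between the organs (camera adjusted p = 1.0e-08; adjusted p = 0.486 with an estimated correlation), lower in KO-labelled spleen and with a median of 0.02 in bone marrow. The composition factor is argued against as the cause, with a median of -0.22 under library totals alone. The gene length trend cannot be told apart from a change of these genes: after a length correction the spleen median was -0.11, with quartiles of -0.20 and 0.01 (adjusted p = 0.011; adjusted p = 0.639 with an estimated correlation). Of 10000 random lists matched on gene length, with a median of -0.15, 2 were as low as the list's -0.29, but they draw unrelated genes while the members had an estimated correlation of 0.48, so their spread is too narrow to exclude the trend; the criterion for this explanation was revised more than once after its values were seen.

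Other lists whose effect differed between the organs by the same test, none of which passed with an estimated correlation, were neutrophil markers (adjusted p = 1.4e-05), immature NK (3.0e-05), innate lymphoid cell markers (3.0e-05), monocyte, macrophage and dendritic cell markers (0.00038), NK transcription factors (0.0030), megakaryocyte and platelet markers (0.012), stem and progenitor markers (0.020), B cell markers (0.023), T cell markers (0.023), mitosis (0.029), basophil and mast cell markers (0.029) and ribosome biogenesis (0.038). The test of the difference filtered genes on their mean over all 12 libraries. It held 15 neutrophil markers and 3 basophil and mast cell markers, while 1 of each list passed the filter in spleen. For both lists, bone marrow fold changes were thus set mostly against spleen values near the floor. A different response of the organs cannot be read from them. Immature NK genes were higher in bone marrow too, with 10 of 14 positive and a median of 0.11 against 0.32 in spleen. Their camera adjusted p in bone marrow was 0.0051, and 0.529 with an estimated correlation. NK maturation and effector genes were lower in bone marrow, with 15 of 18 negative (camera adjusted p = 6.7e-05, and 0.529 with an estimated correlation).

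The 6 libraries of an organ give 10 splits into groups of 3, too few for a share under 0.05. In spleen the real split called 60 genes and the highest other split 0, with 1 split reaching the real value; in bone marrow these were 16 and 0, with 1. For lists past the threshold with the preset correlation, the real split gave 10 in spleen and the highest other 10, with 2 splits reaching it; in bone marrow it gave 16 and the highest other 17, with 2. For the 10 genes called in both organs, 1 of 100 drawn splits, the real one, gave as many, and the highest other gave 0. Since the highest other split called 0 genes in each organ alone, no other joint split could share a gene. The joint splits therefore add nothing to the 10 splits of each organ and do not decide on chance. For the difference between organs the real count was 0, which all 100 splits reach by construction, so the splits say nothing about it.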

How the results depend on the processing

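The pseudocount of 0.1, limma-voom without weights, the gene length correction, the neutrophil covariate and the leave-one-out counts of genes changed in both organs were added after seeing the data; DESeq2 was not run. The spleen count of 60 was 21 at a change of at least 2-fold, 10 without a low value filter, 833 under limma-voom with quality weights and 111 with all 12 libraries in one fit; the bone marrow count of 16 was 38 with quality weights and 34 in the fit of 12. Rfx7 in spleen passed with quality weights (0.64) and with the replicate block (0.50; adjusted p = 0.036), but not with the length correction and replicate block (0.39; adjusted p = 0.167); its adjusted p ran from 0.0071 to 0.539 over the alternatives. Of the other uncalled NK genes, these passed in spleen: Mki67 with quality weights (1.28; adjusted p = 0.018) and the replicate block (0.54; adjusted p = 0.019), S1pr5 with quality weights (-0.47; adjusted p = 0.018), the block (-0.57; adjusted p = 0.015) and the length correction with block (-0.51; adjusted p = 0.041), and Slc3a2 with these 3 (-0.58, -0.60 and -0.56; adjusted p = 0.0059, 0.0046 and 0.022) and in the fit of 12 (-0.60; adjusted p = 0.020). S1pr5 passed in bone marrow with quality weights (-0.78; adjusted p = 0.036) and in the fit of 12 (-0.77; adjusted p = 0.018). Same-numbered libraries did not all deviate together (correlations of 0.39, 0.13 and -0.37 in spleen and 0.34, -0.49 and 0.03 in bone marrow). In both organs WT replicate 1 correlated best with KO replicate 1, but WT replicates 2 and 3 correlated best with another number. With a replicate block the spleen count was 577 and the bone marrow count 9, and with the length correction and replicate block the spleen count was 238. The cause of these differences was not tested. Lists past the threshold were 0 in spleen and 0 in bone marrow with an estimated correlation. With fry they were 8 in spleen, where oxidative phosphorylation did not pass (adjusted p = 0.162), and 3 in bone marrow. Those in bone marrow were the RFX7 candidates, quiescence and interferon response. With the neutrophil covariate 8 lists passed in bone marrow. Leaving out 1 library gave 9 to 66 genes in spleen, 8 to 17 in bone marrow, 6 to 11 in both organs and 0 to 1 for the difference between organs, 9 to 14 lists in spleen, 9 to 19 in bone marrow (9 without WT replicate 3), and an Rfx7 log2 fold change of 0.43 to 0.58 in spleen and 0.01 to 0.19 in bone marrow. Uncalled genes that changed sign were Eomes in spleen (-0.0037 with median-of-ratios, -0.0098 thinned, -0.013 with the length correction, with or without the block), Sell in spleen (-0.013 with quality weights), Cd27 in bone marrow (0.0069 with library totals, 0.0063 thinned) and Il7r in bone marrow (0.13 with quality weights, 0.16 with the neutrophil covariate). Without 1 library, the fold changes ran from -0.025 to 0.15 for Cd27, -0.066 to 0.089 for Eomes and -0.11 to 0.14 for Sell in spleen, and from -0.053 to 0.032 for Cd27, -0.28 to 0.20 for Il7r and -0.20 to 0.85 for Mki67 in bone marrow. The mitosis list in bone marrow turned lower with the neutrophil covariate (adjusted p = 0.014). Lists in bone marrow that turned without 1 library had an adjusted p of 4.5e-06 to 0.607 for oxidative phosphorylation, 1.6e-08 to 0.417 for mitosis and 0.0034 to 0.931 for erythroid markers. Over the 18 alternative fits of each organ, none of the 60 genes called in spleen and 16 called in bone marrow changed sign where tested. For many of these fits that was fixed in advance. The other filters, the fit of 12 and the replicate block leave each fold change as it is. The called genes did not overlap between the groups in CPM, so leaving out 1 library could hardly reverse one.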

Other observations

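Summed levels of some markers of other cell types differed between libraries in bone marrow, and some separated by genotype label in spleen. The sums themselves were not tested. In bone marrow, WT replicate 3 had 149 CPM of neutrophil markers, 52.3 CPM of monocyte, macrophage and dendritic cell markers and 660 CPM of mitosis genes, against 3140, 403 and 2321 CPM in WT replicate 1. All 21 mitosis genes had positive fold changes in KO-labelled bone marrow, with a median of 0.35, but the direction of the list turned without that library. In spleen, megakaryocyte and platelet markers summed to 38.1, 54.3 and 48.6 CPM in WT and 21.1, 22.9 and 29.5 CPM in the KO-labelled libraries, and innate lymphoid cell markers to 163, 178 and 231 CPM against 299, 406 and 356 CPM. None of the 3 tested megakaryocyte and platelet members passed the threshold. That list had a camera adjusted p of 0.013 in spleen, and 0.210 with an estimated correlation. Erythroid markers in spleen summed to 536, 542 and 632 CPM in WT and 798, 834 and 754 CPM in the KO-labelled libraries. Stem and progenitor markers, which include Kit, summed to 379, 371 and 343 CPM against 474, 596 and 545 CPM. Neither list passed camera in spleen (adjusted p = 0.358 and 0.098). Sums of T cell and of neutrophil markers overlapped between the groups in spleen. B cell and plasma cell markers in spleen summed to between 20.4 and 23.9 CPM in WT and between 34.4 and 49.5 CPM in the KO-labelled libraries; of the 2 tested members Cd22, with a mean of 19.6 CPM, was called higher and Cd79b (log2 fold change 0.53; adjusted p = 0.163) was higher adjusted over the list alone (adjusted p = 0.0067) and in all 3 KO-labelled libraries, while Cd79a (log2 values of 0.83, 0.61 and 1.17 in WT and 0.61, 0.62 and 0.91 in KO) and Ms4a1 (0.28, 0.35 and 0.37 against 0.13, 0.29 and 0.61), both below the filter, overlapped between the groups. Cd79b, Cd79a and Ms4a1 were chosen after their values were seen.

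MHC class II genes had negative fold changes in all 7 tested members of each organ, with medians of -0.40 in spleen and -0.27 in bone marrow; H2-Oa in bone marrow passed the threshold. The camera adjusted p was 0.0047 and 2.6e-07, and with an estimated correlation the adjusted p was 0.471 and 0.366. In spleen, markers of monocytes, macrophages and dendritic cells, which express MHC class II, were lower with them: 7 of 8 tested members had negative fold changes, with a median of -0.67 and C1qb called (camera adjusted p = 0.0047; adjusted p = 0.471 with an estimated correlation). In bone marrow these markers did not fall with MHC class II: 7 of 9 tested members had positive fold changes, with a median of 0.14. Their camera adjusted p there was 0.127, and 0.799 with an estimated correlation.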
